A study of Mus musculus with 4 samples.

How the data were processed

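H4K20me1 and non-immune serum immunoprecipitations of the MSC21 mesenchymal stem cell population and of the clone 4L.1.4 gave 4 libraries, 1 of each kind per culture. Per the labels' protocols, cells were grown to confluence, fixed and sonicated, libraries were amplified for 12 cycles, and each was sequenced on 1 lane as single reads of 50 cycles. The submitters' processing notes name CASAVA 1.8.1, Bowtie and the mouse build mm9, without saying which did what. The peak caller, its settings and the use of the serum libraries as its control are not given in the sources used here.

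The authors deposited 2 lists of regions, each with 3 columns (chromosome, start and end in base pairs) and no header. Each list was taken as the H4K20me1 regions of the culture it is named for. The names carry the tag FDR5, read here as a false discovery rate of 5%, although its meaning is not stated. No replicates were pooled, since there was 1 H4K20me1 library per culture. Starts were read as counted from 0, as in BED files, and are printed counted from 1. Regions within a list did not overlap. The number and width of called regions generally depend on sequencing depth and enrichment, which the lists do not give.

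Genes could not be assigned. The gene table at hand described GRCm38.p6, and 121 population and 65 clone regions on chromosome 7 lay beyond the last gene of that chromosome in it, so the builds differ. Coordinates were not converted between builds. The planned comparisons of genes with a region, of gene lists fixed before the data were examined, and of region positions relative to genes were therefore not made. The planned rule for items to name then reduced to the 10 widest regions of each list; the rule's other part, the best-scored regions, could not be applied without scores. Other regions named in the closing section were chosen after their values were seen.

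Computations used Python 3.11.15, numpy 2.4.6 and scipy 1.17.1. For each list the number of regions, covered base pairs and widths were taken. A region counted as overlapped when it shared at least 1 bp with a region of the other list, and shares have exact Clopper-Pearson 95% intervals. These cover counting error only and take regions as independent. The share given by chance was taken from 1000 random placements of the other list, in which each region kept its width and chromosome and fell anywhere between the first and last region of either list on that chromosome. Placements in which each chromosome's list was rotated, or moved as a whole by 200000 to 2000000 bp, were added after seeing the data, and overlap by width class used 100 placements. The clone share of a chromosome is clone regions divided by clone plus population regions. Because regions cluster, its interval is 1.96 standard errors either side, from a jackknife that leaves out 1 block of 10 Mb at a time. Bins of 1 Mb were used for regional coverage and segments of 20 Mb for trends within a chromosome. None of these intervals includes variation between cultures or libraries.

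The alternatives fixed before the data were examined were joining regions within 1000 or 10000 bp, autosomes only, stricter or looser overlap, and covered base pairs in place of regions. Those that ranked regions by score could not be run. In their place, the wider 50% of each list, the population list reduced to its 11812 widest regions (ties at 2636 bp included) and a minimum width of 2000 bp were added after seeing the data. The interval functions were tested on simulated data, where they differed from a direct count in 0 of 200 random pairs of lists. In a simulated list made from 16557 of the 28166 population regions all 16557 were recovered. Those regions were copied unchanged, so working code had to recover them, and shifted or split regions were not simulated.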

Results

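H4K20me1, the monomethylated form of lysine 20 of histone H4, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse bone marrow mesenchymal stem cells of the C57BL/6 strain. H4K20me1 is a chromatin mark known from the bodies of transcribed genes and from the inactive X chromosome. The study set a mixed culture, the MSC21 population, beside 4L.1.4, a clone derived from it. Each was represented by 1 immunoprecipitation with an H4K20me1 antibody and 1 with non-immune rabbit serum, so 4 libraries in all and 1 per group. The values analysed were 2 lists of H4K20me1 regions, 1 for the population and 1 for the clone, in mm9 coordinates. The lists hold positions only, with no read count, enrichment or significance per region, so the sequencing depth behind each region is unknown. With 1 library per group no difference between the cells could be set against replicate error. No p-value is given, and all intervals cover counting error or the unevenness along chromosomes within these libraries.

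The first comparison asked how much of the genome carried the mark in each culture. The population list held 28166 regions covering 135.3 Mb, and the clone list held 11809 regions covering 73.6 Mb. The population therefore had 2.39 times as many regions and 1.84 times as many covered base pairs. With a minimum width of 2000 bp, chosen after seeing the data, 14733 population and 9582 clone regions were left, a smaller gap. Both lists spread over the 19 autosomes and the X chromosome, and neither held a region on the Y chromosome. Wide regions carried much of the marked sequence in both: regions of at least 10000 bp made up 11.9% of the population regions and 51.0% of the covered base pairs, against 17.0% and 49.6% in the clone. In number of regions, the proportions of the lists differed among narrow regions. The narrowest 1% of regions reached up to 702 bp in the population and 1269 bp in the clone. The settings of the calls are not given, so unlike settings cannot be told apart here from a difference between the cultures. In the population 9608 regions (34.1%) were under 1500 bp wide, whereas in the clone 525 (4.45%) were, and the median width was 2122.5 bp in the population (quartiles 1248 and 4838.75 bp) and 3680 bp in the clone (quartiles 2254 and 7310 bp). The population list kept more regions after neighbours within 10000 bp had been joined, with 9714 joined regions against 5698, a ratio of 1.70.

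**Figure D1:**
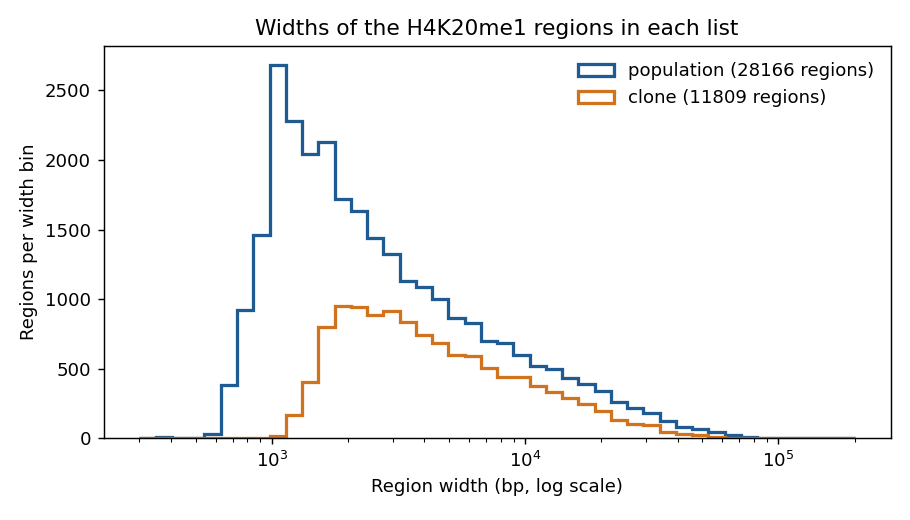
Number of H4K20me1 regions per width bin (y axis) against region width in bp on a log scale (x axis) for the population (blue) and the clone (orange). The population list extends to narrower regions, with 3170 regions under 1000 bp against 8 in the clone.

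The widest single regions lay in the population. Its widest region spanned 166.6 kb on chromosome 5 (119010932 to 119177550), and the clone list had no region within 303.9 kb of it. A region of 110.9 kb on chromosome 3 (21976940 to 22087845) also had no clone counterpart, the nearest clone region being 1922 kb away. On chromosome 8 a population region of 145.3 kb (125419923 to 125565243), and on chromosome 5 another of 91.9 kb (148242727 to 148334624), were not overlapped either, although clone regions lay 1.52 kb and 1.95 kb from their ends. The other 6 of the 10 widest population regions were covered in part. Coverage by clone regions was 8.09% for 148.0 kb on chromosome 1 (91353782 to 91501762), 1.85% for 121.5 kb on chromosome 13 (94851145 to 94972677) and 9.56% for 120.6 kb on chromosome 4 (130219664 to 130340260). It was 64.8%, in 13 separate clone regions, for 115.4 kb on chromosome 4 (148357278 to 148472707), 18.97% for 94.2 kb on chromosome 4 (8618996 to 8713165), and 38.4% for 92.3 kb on chromosome 16 (38097384 to 38189672).

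The 10 widest clone regions were narrower, from 59.4 to 87.1 kb, and each was shared with the population. Population regions covered between 54.4% and 99.99% of them, with a median of 97.6%. The widest lay on chromosome 18 (83084258 to 83171366, 87.1 kb, 99.3% covered), followed by chromosome 17 (32338324 to 32421205, 82.9 kb, 98.5% covered) and chromosome 6 (113027975 to 113110244, 82.3 kb, 54.4% covered). Those on chromosome 5 (122162930 to 122237964, 125589822 to 125659305 and 115461624 to 115520981) were covered to 96.7%, 99.96% and 99.99%. Those on chromosome 2 (27742683 to 27814732 and 27534406 to 27595106) were covered to 94.7% and 96.5%. The region on chromosome 1 (39959597 to 40023831) was covered to 99.9%, and the region on chromosome 7 (137333855 to 137407313) to 63.6% by 9 population regions.

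The second comparison asked whether the clone carried the mark at the same places as its parent population. Most clone regions lay on marked sequence of the population: 10011 of 11809 (84.8%, exact Clopper-Pearson 95% interval 84.1 to 85.4%) shared at least 1 bp with a population region. The reverse held for 9481 of 28166 population regions (33.7%, 33.1 to 34.2%), which left 18685 population regions without a clone counterpart at the authors' threshold. Many of these were narrow: 375 of 3170 population regions under 1000 bp, and 1713 of 10263 at 1000 to 2000 bp, were overlapped. With the population list reduced to its 11812 widest regions, a setting chosen after seeing the data that shortens the list and removes narrow regions at once, 56.1% of its regions and 71.1% of the clone regions were overlapped. In base pairs, 60.8 Mb was common to both lists, which was 82.6% of the clone's marked sequence and 44.97% of the population's. The common part made up 41.1% of the union of 148.1 Mb. Sequence marked in the population alone came to 74.4 Mb and in the clone alone to 12.8 Mb. A region absent from a list was not called there, which does not show that the mark was absent.

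These overlaps exceeded those of randomly placed regions. When each region of the other list was placed at random within its chromosome, 1000 times, the median share overlapped was 12.0% for clone regions (range 10.6 to 13.2%) and 5.26% for population regions (range 4.72 to 6.05%). The observed shares were 7.07 and 6.40 times these medians. Moving each whole chromosome list by 200000 to 2000000 bp, which keeps the spacing of the regions and roughly the neighbourhood, gave medians of 13.2% and 6.44%, and rotating each list along its chromosome gave 9.27% and 4.53%. No placement of any of these 3 kinds reached the observed shares. With a reciprocal overlap of at least 50% the shares were lower, at 45.2% of clone regions and 18.96% of population regions.

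Wider regions were overlapped more often, as were wider regions under random placement. Of the population regions under 1000 bp, 11.8% (10.7 to 13.01%) were overlapped by the clone, rising through 33.7% (32.7 to 34.8%) at 2000 to 5000 bp to 77.1% (75.3 to 78.9%) at 10000 to 20000 bp. From 20000 bp on, the share was 79.1% (76.7 to 81.3%). Random placement gave medians of 3.36% in the narrowest of these classes and 17.2% in the widest. Clone regions were overlapped in 77.0% (75.2 to 78.8%) of cases at 1000 to 2000 bp and 96.8% (94.97 to 98.1%) from 20000 bp on, against 7.17% and 33.7% under random placement. Where 1 clone region met exactly 1 population region (5204 pairs), their starts differed by a median of 385.5 bp and their ends by 423 bp. Within these pairs the clone region was the wider in 37.4%, and the median ratio of clone to population width was 0.94 (log2 ratio -0.08, quartiles -0.59 and 0.13), although the clone list as a whole had the larger median width.

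**Figure D2:**
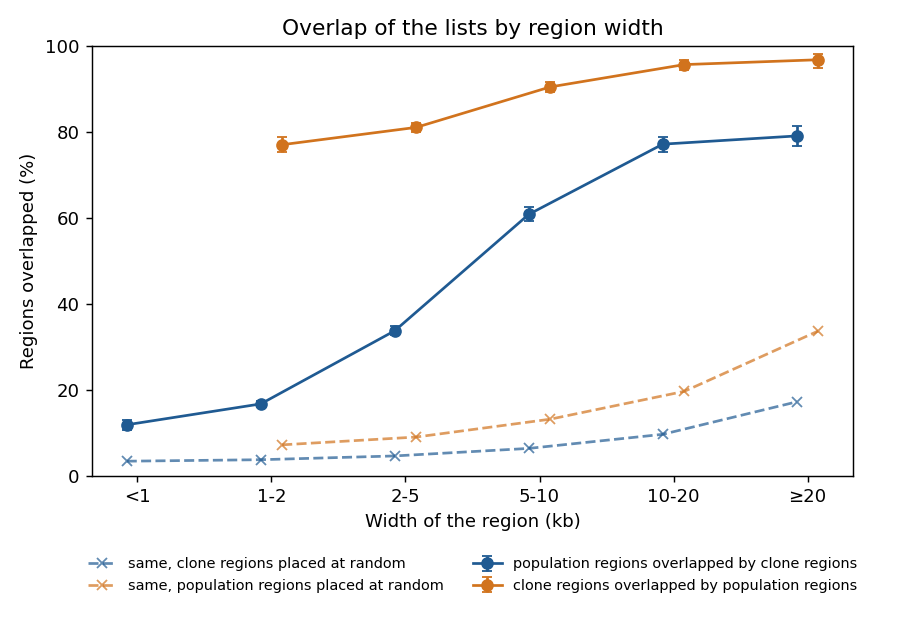
Share of regions overlapped by the other list (y axis, percent) for classes of region width in kb (x axis), for population regions (blue) and clone regions (orange). Circles are observed shares with exact 95% intervals, crosses the median of 100 random placements of the other list; the 8 clone regions under 1 kb are not drawn. The population share goes from 11.8% in the narrowest class to 79.1% in the widest.

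The third comparison asked where along the genome the lists differed beyond their overall sizes. Over all chromosomes the clone contributed 29.5% of the regions of both lists. On chromosome 13 the clone share was 18.3% (95% block jackknife interval 15.1 to 21.5%, from 1267 population and 284 clone regions), the lowest of the 20 chromosomes. It was 19.9% on the X chromosome (16.4 to 23.4%, 894 and 222 regions) and 23.1% on chromosome 16 (19.3 to 26.9%, 1012 and 304 regions). Shares above the overall value were found on chromosome 11 (34.3%, 32.1 to 36.4%), chromosome 5 (33.2%, 30.5 to 35.9%) and chromosome 8 (33.0%, 30.8 to 35.2%). Chromosome 19 was also above it in regions (33.7%, 31.4 to 36.0%) but not in covered base pairs, where its clone share was 34.9% against 35.3% overall. The remaining 13 chromosomes had intervals that included the overall share; 1 of 20 intervals would be expected to leave it out by chance.

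On chromosome 13 the clone list, and not the population list, stood apart from the autosomal average. Population regions covered 54.5 kb per Mb of chromosome 13, close to the 55.2 kb per Mb over all autosomes, while clone regions covered 13.4 kb per Mb against 30.3 kb per Mb. This was the lowest clone density of any autosome. Of the chromosome 13 population regions, 14.9% were overlapped by the clone, the lowest share of any chromosome. This share was 33.7% over all chromosomes and highest, at 47.0%, on chromosome 11. The next lowest shares were 18.3% on the X chromosome, 21.3% on chromosome 16, 23.6% on chromosome 3 and 23.8% on chromosome 15. The clone-share intervals of chromosomes 3 and 15 included the value over all chromosomes. Conversely, 91.5% of the clone regions on chromosome 13 were overlapped by the population. The X chromosome was sparsely marked in both lists, with 19.8 kb per Mb in the population and 7.28 kb per Mb in the clone, below the lowest autosome of each (29.3 and 13.4 kb per Mb).

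**Figure D3:**
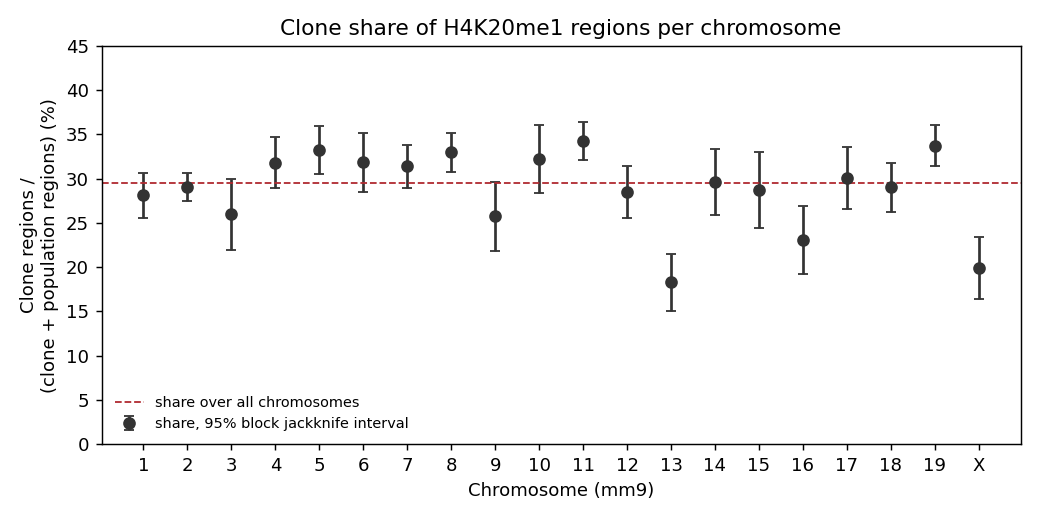
Clone regions as a percentage of clone plus population regions (y axis) for each chromosome (x axis). Points are shares, bars 95% block jackknife intervals over 10 Mb blocks, and the dashed line is the share over all chromosomes, 29.5%; the whole intervals of chromosomes 13, 16 and X lie below it.

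At the scale of 1 Mb the profiles were similar in outline. Of 2570 bins, 1581 held marked sequence in both lists, 265 in the population alone, 9 in the clone alone and 715 in neither. The kilobases covered per bin were correlated across bins (Pearson r = 0.84, Spearman rho = 0.89); bins are not independent replicates and include the empty ones. Within single chromosomes rho ranged from 0.76, on chromosome 13, to 0.95, on chromosome 4. The clone covered more of the bin than the population in 177 of the 1855 bins with any mark (9.54%).

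**Figure D4:**
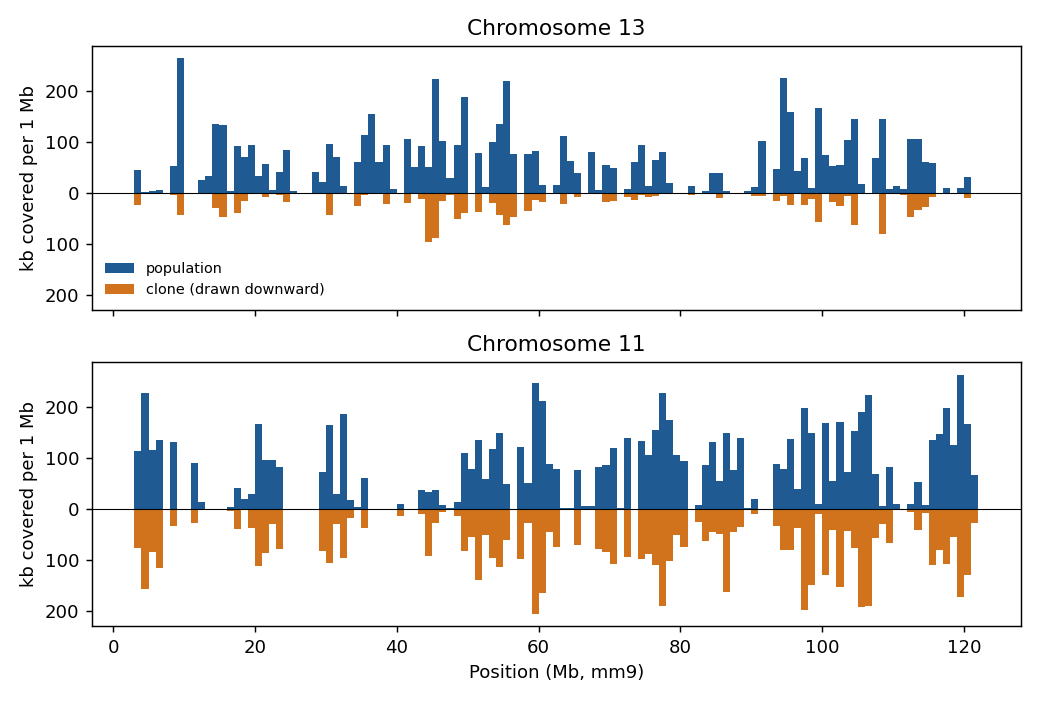
Kilobases covered by H4K20me1 regions in each 1 Mb bin (y axis) along chromosomes 13 and 11 (x axis, Mb), with the population drawn upward in blue and the clone downward in orange. The clone covers 1.57 Mb of chromosome 13 and 6.51 Mb of chromosome 11, against 6.37 and 8.77 Mb in the population. These chromosomes had the lowest and the highest clone share of regions.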

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

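The wider-50%, reduced-list and minimum-width settings below were chosen after seeing the data; the cause of each shift was not tested beyond what the setting itself does. The population list had more regions than the clone under every setting run on both. Joining regions within 1000 bp left 18673 population and 8734 clone regions, and joining within 10000 bp left 9714 and 5698. A minimum of 2000 bp left 14733 and 9582, so the lists differed less in number there than over all widths. The clone numbers 8734 and 9582, and both numbers for autosomes alone, stayed within 1.5 times. The share of population regions overlapped was 37.5% after joining within 1000 bp, 36.0% in the wider 50%, 56.1% with the reduced population list, 46.1% from 2000 bp on, 28.8% when 50% of the region had to be covered, 18.96% with reciprocal overlap and 37.5% when a clone region within 1000 bp sufficed. The share of clone regions overlapped was, in the same order, 86.5%, 86.1%, 71.1%, 79.7%, 79.4%, 45.2% and 86.6%. Common sequence was 38.8% of the union in the wider 50% and 44.2% with the reduced list. Relative to the overall share, the clone share of chromosome 11 was 7.37 percentage points higher in base pairs and 7.10 higher from 2000 bp on, and that of chromosome 13 differed by -15.5 and -17.6 points. Chromosome 19 changed sign, at -0.30 points in base pairs, -1.60 in the wider 50% and -0.16 from 2000 bp on. Of the 55 recomputed values, 28 stayed within their interval or 1.5 times, 24 left it and 3 changed direction. Autosomes alone left every value tested there within its limit. The limit was 1.5 times for region numbers and the exact interval for overlapped shares. For chromosome shares and common sequence it was the wider block jackknife interval. The tally therefore depends on these unlike limits and does not rank the results by stability. The planned rankings by score, and all planned gene-based settings, were not run. The unknown depth limits every statement about unmatched regions. No paired analysis was possible because each group had 1 library.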

Other observations

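The tests of clustering, the overlap of wide regions by chromosome, the overlapped share without adjustment, the comparison among segments and the places named here were chosen after the values behind them had been seen. Although the clone list was the smaller, some stretches were marked more broadly there. On chromosome 15 the bin from 42000001 to 43000000 held 91.7 kb of clone regions and no population region. On chromosome 11 the bin from 44000001 to 45000000 held 92.2 kb in the clone and 33.2 kb in the population, and included a clone region of 50.8 kb (44434209 to 44485012) with no population region within 60.3 kb. A clone region of 49.0 kb on chromosome 4 (63657717 to 63706726) was 433.4 kb from the nearest population region. Further bins with more clone than population sequence lay on chromosome 5 (103000001 to 104000000, 81.4 against 21.7 kb), chromosome 18 (14000001 to 15000000, 94.8 against 35.5 kb) and chromosome 15 (3000001 to 4000000, 84.6 against 25.4 kb).

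The widest joined stretch of the population list lay on chromosome 7, where regions within 10000 bp of each other joined into 532.3 kb (103333756 to 103866102), of which the population marked 475.5 kb and the clone 171.1 kb. The largest excess of the population over the clone in a 1 Mb bin was on chromosome 1 (91000001 to 92000000), with 378.6 against 24.0 kb. In the bin from 94000001 to 95000000 of chromosome 13 the values were 223.6 and 6.46 kb.

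The first pattern weighed was the smaller number of clone regions. Splitting of the same stretches into more pieces in the population is argued against as the whole cause, since joining regions within 10000 bp left a ratio of 1.70 (block jackknife 95% interval 1.64 to 1.77). A less sensitive call of one common profile, from depth, enrichment or threshold, predicted a clone list nested in the population list. Of the clone regions, 9.81% (8.74 to 10.9%) lay more than 5000 bp from any population region, and of those at least 10000 bp wide 3.03% did. The first value fell between the limits of 5% and 10% set beforehand, so it decided neither way. A value above 10% would not have excluded a less sensitive call, since regions can also be missed in the population list. A narrower distribution of the mark in the clone predicts a nested list too. The test therefore could not tell it apart from a less sensitive call. A biological difference between clone and population stays open and untested, because there was 1 library of each.

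The second pattern was the uneven clone share across chromosomes. Clustering of regions within 10 Mb blocks is argued against as the whole cause: 7 of 20 chromosomes had block jackknife intervals that left out the overall share, while dealing the 274 blocks to the chromosomes at random, 1000 times, gave a median of 1 and at most 6 such chromosomes. Clustering over longer distances was not tested. Region width, alone or with the local density of population regions, was tested on another quantity, the share of population regions overlapped by the clone. In it 85.7% of those chromosomes (6 of 7, all but chromosome 19) deviated after each adjustment, as the same number did without one. Of all 20 chromosomes, 11 did after either adjustment against 10 without. For these 6 this argues against both as the whole cause of the uneven overlapped share. The overlapped share did not follow the clone share on every chromosome. Chromosomes 3 and 15 were at -12.2 and -11.7 percentage points after the adjustment for width, while their clone-share intervals included the value over all chromosomes. Whether width or density explains the uneven clone share was therefore not decided by these adjustments. With a minimum width of 2000 bp, chosen after seeing the data, the clone share itself kept its direction on the 6 chromosomes. It was at -17.6 points on chromosome 13, -11.2 on X, -7.33 on 16, 7.10 on 11, 4.26 on 5 and 5.44 on 8. Chromosome 19 was at -0.16. Regions under 2000 bp were thus not needed for the direction on the 6, although no interval is given for these values. In the overlapped share, the adjustment for width moved the deviation from -18.7 to -20.5 points on chromosome 13. It also enlarged the deviation on chromosome 11, from 13.4 to 14.9, and on chromosome 8, from 9.79 to 10.7. On the X chromosome the deviation moved from -15.3 to -10.9, on chromosome 16 from -12.3 to -10.4 and on chromosome 5 from 9.91 to 8.27. Width remains open for part of the deviation on these last 3. GC content, which could not be computed without an mm9 sequence, and a biological difference between the cells stay open.

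A hypothesis is a shift along the whole of chromosome 13, as a change in chromosome copy number would give, in the clone or in part of the population. Population coverage of chromosome 13 gave no sign of a shift in the population, at 54.5 kb per Mb against 55.2 over all autosomes. Single autosomes ranged from 29.3 to 78.3, so this does not exclude one. All 7 of the 20 Mb segments of chromosome 13 had a clone share below that over all chromosomes, from 10.98 to 28.6%. The exact intervals of 6 lay below it, and the last segment held 7 regions. Because chromosome 13 was picked for its low share, this largely restates that observation and would follow from any cause acting along the chromosome, and the segments also differed among themselves (10.98%, 7.36 to 15.6%, at 20 to 40 Mb against 23.9%, 19.8 to 28.3%, at 40 to 60 Mb), so the hypothesis stays open. On chromosome 16 all 5 and on the X chromosome all 9 segments were below, but with intervals below in 2 and 4 of them. Among population regions of at least 10000 bp, 62.7% (54.4 to 70.4%) were overlapped on chromosome 13 against 78.5% (77.1 to 80.0%) elsewhere, while chromosome 16 (75.2%, 66.0 to 83.0%) and the X chromosome (45 of 60 regions, 62.1 to 85.3%) had intervals that included the latter value. The intervals for segments and wide regions are exact ones that take regions as independent, so clustering can make them too narrow. For the clone share of whole chromosomes, 12 of 20 exact intervals left out the share over all chromosomes, against 7 from the block jackknife.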
